A study of Saccharomyces cerevisiae with 15 samples.

How the data were processed

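RNA from 15 yeast cultures was measured on 1 type of array (Affymetrix YG-S98), in 5 groups of 3 biological replicates that were assigned from the sample titles. Per the labels, cells were grown logarithmically in synthetic dextrose medium, and biotinylated cRNA was prepared from 10 ug of total RNA. The deposited table holds linear intensities, with 1 value per probe set and array. The software that made these intensities, its background correction and its scaling are not given in the sources used here. The trimmed mean of the values (2% at each end) was 500.5 to 500.7 on every array, so the arrays had been scaled to a common level before they were deposited. Total signal was 6839487 to 7739820 per array, and 0 to 4 probe sets per array had a value of 0. No detection calls were in the table.

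The table has 9335 probe sets, of which 60 controls were left out and 9275 tested. Of these, 6504 matched 1 gene, 328 several and 2443 none in the platform annotation, and together they covered 5656 genes. Gene names were brought up to date with the reference gene table. A gene with several probe sets was represented by the brightest. The rule fixed before the data were examined was to use quantile normalisation if the array medians differed by a factor above 1.2. The medians of the linear values differed by a factor of 1.219. The medians of log2(value + 16) differed by 0.254, where the limit was written as 0.26. The added 16 makes that difference smaller than the log2 of the linear ratio. The choice lay close to its limit. The linear form of the limit was applied, and values were quantile normalised and converted to log2(value + 16). The results with the values as deposited are given below.

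Group means were compared with limma 3.58.1 in R 4.3.3, with 1 fit to all 15 arrays, 10 residual degrees of freedom and a prior of 5.35 degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over 9275 probe sets in each comparison, and an adjusted p under 0.05 was called. Fold changes are log2 differences, first group minus second, with the moderated standard error (SE). An interaction was tested as the difference between the fusion's effect with and without the deletion. The groups, 10 comparisons, threshold, gene lists and naming rule were fixed before the data were examined, and an additional comparison, between the groups of the second spike-in set, was added after the data were seen.

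Gene lists were written from general knowledge of yeast before the values were examined. They hold 700 genes, of which 658 were measured, and the 3 PDR lists hold 24, of which 22 were measured. Of 34 lists, 33 were tested with limma's camera with a preset correlation of 0.01, adjusted over 330 tests of lists and comparisons. Camera was repeated with the correlation estimated from the data, and the rotation test fry was also run. With the preset correlation 127 of 330 list tests were called, with fry 102, and with an estimated correlation 0 in camera, where 61 had an unadjusted p under 0.05 and the lowest adjusted p was 0.0656. No list call of the 10 fixed comparisons held with an estimated correlation. The additional comparison is outside these 330 tests. Its list tests were adjusted over its own 33 tests, so their adjusted p-values are not on the same scale.

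Genes were named by rule: the target genes in every group, PDR genes, the called genes with the largest rise and fall without overlap between the groups (8 each way in the first 4 comparisons, 3 in the others), and up to 4 members of each called list. For 3 against 3 arrays, 10% of unchanged genes would show no overlap. Array sets were read from the BioB and BioC spike-ins, whose difference was seen only when the data were examined.

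The procedure was tested on simulated data with the spread of each probe set and no correlation between genes. Of 200 genes changed 2-fold 23.0% were recovered with 5 false calls, and of 200 changed 4-fold 96.5% with 12 false calls. In that test 1 of 33 lists was called, the one that had been shifted. The alternatives were the values as deposited, median centring, leaving out the dimmest probe sets (lowest 25% by mean), a pseudocount of 1 or 64, an intensity trend with a robust prior, a fit of only the groups compared, the replicate number as a block, and leaving out each array in turn. Array weights, leaving out the 3 arrays lowest in ribosome assembly genes, and a fit of only the first spike-in set were added after the data were seen. Leaving out those 3 arrays leaves 1 deletion array, which is assumed to vary like the other groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.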

Results

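Transcript levels of the budding yeast Saccharomyces cerevisiae were measured on Affymetrix YG-S98 arrays, with 1 array for each of 15 cultures in logarithmic growth in synthetic dextrose medium. The cultures formed 5 groups of 3 biological replicates: an empty vector, a fusion of Pdr1 to Cyc8, a fusion of Pdr1 to Sin3, a deletion of PDR1, and the deletion carrying the Pdr1-Cyc8 fusion. Pdr1 is a zinc cluster transcription factor that activates pleiotropic drug resistance (PDR) genes, among them membrane pumps of the ABC family, and Cyc8 and Sin3 are subunits of corepressor complexes. The median signal of an array lay between 116.1 and 141.5, and 835 to 1364 of the 9335 probe sets on an array had a signal under 16. The number of arrays limits the precision of every value.

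The arrays fell into 2 sets by their hybridisation spike-ins. The BioC control exceeded the BioB control by 1.02 to 1.32 on the log2 scale on the 9 arrays of the empty vector, Pdr1-Cyc8 and deletion groups, and differed from it by -0.64 to -0.20 on the 6 arrays of the Pdr1-Sin3 and Pdr1-Cyc8-in-deletion groups. No group spanned both sets, so a comparison between sets does not by itself separate a group difference from a difference between sets. Comparisons among the empty vector, Pdr1-Cyc8 and deletion groups lay within the first set. Cultures also differed within groups: against the empty vector, ribosome assembly genes averaged -1.11 ± 0.86 (SD, n = 3) in the deletion, with single cultures from -1.71 to -0.13, and -0.76 ± 0.47 with Pdr1-Cyc8. The corresponding means were -0.70 ± 0.08 with Pdr1-Sin3 and -0.05 ± 0.04 with Pdr1-Cyc8 in the deletion.

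The genes named in the design were examined first. PDR1 had a mean log2 level of 9.08 ± 0.16 (SD, n = 3) with the empty vector, 9.07 ± 0.12 with Pdr1-Cyc8, 8.67 ± 0.23 with Pdr1-Sin3, 4.70 ± 0.40 in the deletion and 6.94 ± 0.24 with Pdr1-Cyc8 in the deletion. CYC8 rose from 8.69 ± 0.06 with the empty vector to 12.26 ± 0.30 with Pdr1-Cyc8 and to 11.58 ± 0.52 with Pdr1-Cyc8 in the deletion, against 8.82 ± 0.40 in the deletion alone and 8.66 ± 0.17 with Pdr1-Sin3. SIN3 rose from 8.21 ± 0.09 to 11.45 ± 0.13 with Pdr1-Sin3, and was 8.34 ± 0.23, 8.39 ± 0.33 and 8.32 ± 0.26 with Pdr1-Cyc8, in the deletion and with Pdr1-Cyc8 in the deletion. Which parts of PDR1, CYC8 and SIN3 the constructs hold is not given in the sources used here, so the probe sets may read a fusion, the endogenous gene or both. The level of PDR1 in the deletion was near the floor of the scale, so its fold change depended on the pseudocount: the difference from the empty vector was -4.37 on the scale used, -5.72 with a pseudocount of 1 and -2.98 with 64.

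**Figure D1:**
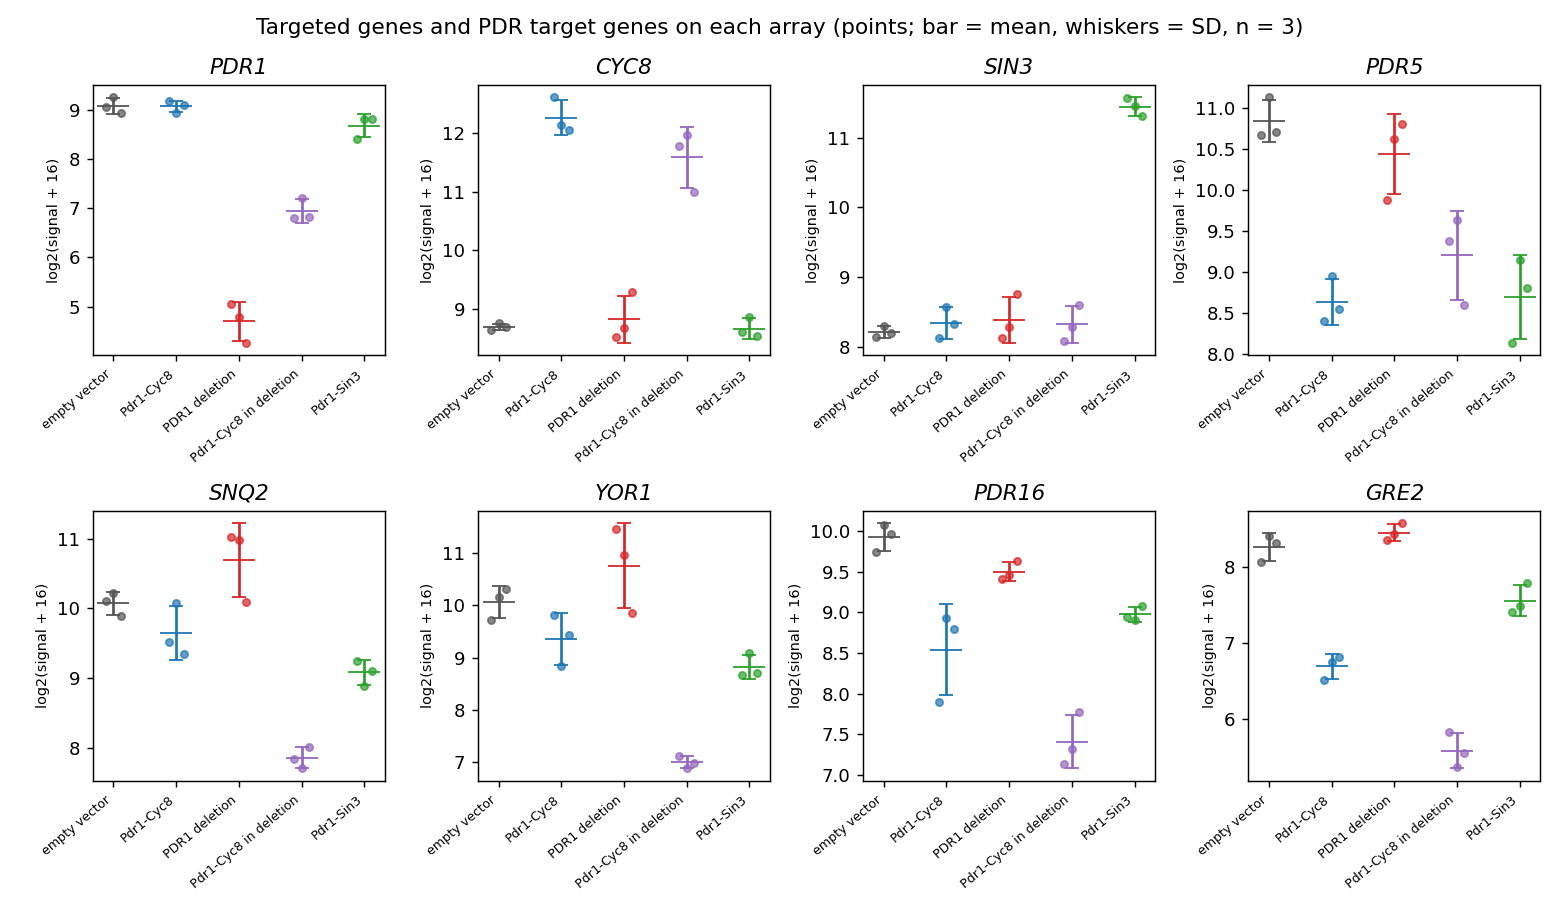
Log2 level (y axis, log2 of signal plus 16) of target and PDR genes in each group (x axis), with a point per array, the mean of 3 arrays and its SD. PDR5 lay at 10.84 with the empty vector and at 8.63 with Pdr1-Cyc8, and PDR1 at 4.70 in the deletion.

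Whether Pdr1-Cyc8 represses PDR genes in cells that keep PDR1 was addressed by comparing it with the empty vector. PDR5, the major drug efflux pump of the plasma membrane, fell by 2.21 on the log2 scale (SE 0.326, limma adjusted p = 0.0044), from 10.84 ± 0.26 to 8.63 ± 0.28 (SD, n = 3 each). GRE2, which encodes an NADPH-dependent reductase, fell by 1.58 (SE 0.198, adjusted p = 0.00106), and PDR16, a phosphatidylinositol transfer protein, fell by 1.39 (SE 0.256, adjusted p = 0.0188). These 3 were the members called among 22 measured PDR targets, of which 19 had values below 0; 10 were lower when adjusted over the list alone. The pumps SNQ2 and YOR1 did not pass, with values of -0.42 (adjusted p = 0.634) and -0.70 (adjusted p = 0.52). By camera, the PDR lipid genes were lower (mean -1.04, adjusted p = 4.83e-05, adjusted p = 0.0656 with an estimated correlation), with 1 of 5 members called and 3 adjusted over the list alone. The PDR transporters (adjusted p = 0.0408, adjusted p = 0.38 with an estimated correlation) had 1 of 6 lower by either count, and the other PDR targets (adjusted p = 1.33e-05, adjusted p = 0.165 with an estimated correlation) had 1 of 11 called and 6 lower adjusted over the list alone. PDR16 lost its call without empty vector replicate 1, 2 or 3 or Pdr1-Cyc8 replicate 1 (adjusted p = 0.0553, 0.0768, 0.0693 and 0.0904, from 0.0108 to 0.174 over all alternatives).

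Outside the PDR lists, Pdr1-Cyc8 raised SHC1, a regulator of chitin synthesis, by 2.84 (SE 0.243, adjusted p = 1.42e-05), the flocculin FLO1 by 2.46 (SE 0.401, adjusted p = 0.00871), GSY1, a glycogen synthase, by 2.41 (SE 0.363, adjusted p = 0.00492), and HXT6, a high-affinity glucose transporter, by 2.09 (adjusted p = 0.0044). MIG2, a repressor that acts in glucose repression, fell by 2.28 (SE 0.315, adjusted p = 0.00259). The phosphate transporter PHO84 (-3.67, SE 0.716, adjusted p = 0.0261) and the acid phosphatase PHO5 (-2.10, SE 0.435, adjusted p = 0.034) also fell. Environmental stress genes were higher as a list, with 5 of 33 called, 17 higher and 1 lower adjusted over the list alone, and a mean of 0.81 (camera adjusted p = 2.12e-15, adjusted p = 0.0906 with an estimated correlation). Among 25 glucose-repressed genes 3 rose, and 6 were higher and 1 lower adjusted over the list alone (camera adjusted p = 6.4e-05, adjusted p = 0.0906 with an estimated correlation). Of 16 phosphate genes 2 fell, 7 adjusted over the list alone (camera adjusted p = 4.68e-05, adjusted p = 0.214 with an estimated correlation). Of 23 sphingolipid synthesis genes 2 fell, SUR2 (-1.46, adjusted p = 0.00871) and LAC1 (-1.33, adjusted p = 0.0121), and 3 adjusted over the list alone (camera adjusted p = 0.0148, adjusted p = 0.266 with an estimated correlation). Ribosome assembly genes were lower as a list (mean -0.76, camera adjusted p = 1.24e-16, adjusted p = 0.397 with an estimated correlation), although limma called 0 of 60, over all probe sets or adjusted over the list alone.

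In all, Pdr1-Cyc8 raised 43 and lowered 23 of 9275 probe sets against the empty vector (limma, adjusted p under 0.05). Leaving out 1 array gave 22 calls without empty vector replicate 1, 32 without its replicate 3, 18 without Pdr1-Cyc8 replicate 1 and 43 without its replicate 2. Of 17 genes named by size or as PDR targets and called, 9 stayed called whichever array was left out (CYC8, PDR5, GRE2, SHC1, FLO1, GSY1, YHR033W, MIG2 and PGA3). PHO84 lost its call without empty vector replicates 1 or 3 or Pdr1-Cyc8 replicates 1 or 3 (adjusted p = 0.146, 0.112, 0.156 and 0.0643, from 0.00623 to 0.221 over all alternatives). PHO5 lost it without any of these (0.166, 0.14, 0.193 and 0.0789) or Pdr1-Cyc8 replicate 2 (0.07), with 0.00116 to 0.258 over all alternatives. SUR2 lost its call without empty vector replicate 1 (adjusted p = 0.0564, from 0.00322 to 0.0581), and LAC1 without that array or Pdr1-Cyc8 replicates 1 or 2 (0.0803, 0.0679 and 0.0521, from 0.00422 to 0.0863). FLO1, MIG2 and HXT6 lost their calls in a fit of only these groups (highest adjusted p over all alternatives 0.116, 0.0664 and 0.0863). Without the 3 arrays lowest in ribosome assembly genes (deletion replicates 1 and 2 and Pdr1-Cyc8 replicate 1), 40 probe sets were called, and 19 with only the first set of arrays in the fit. A pseudocount of 1 gave 36, a fit of only these groups 10 and array weights 109.

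**Figure D2:**
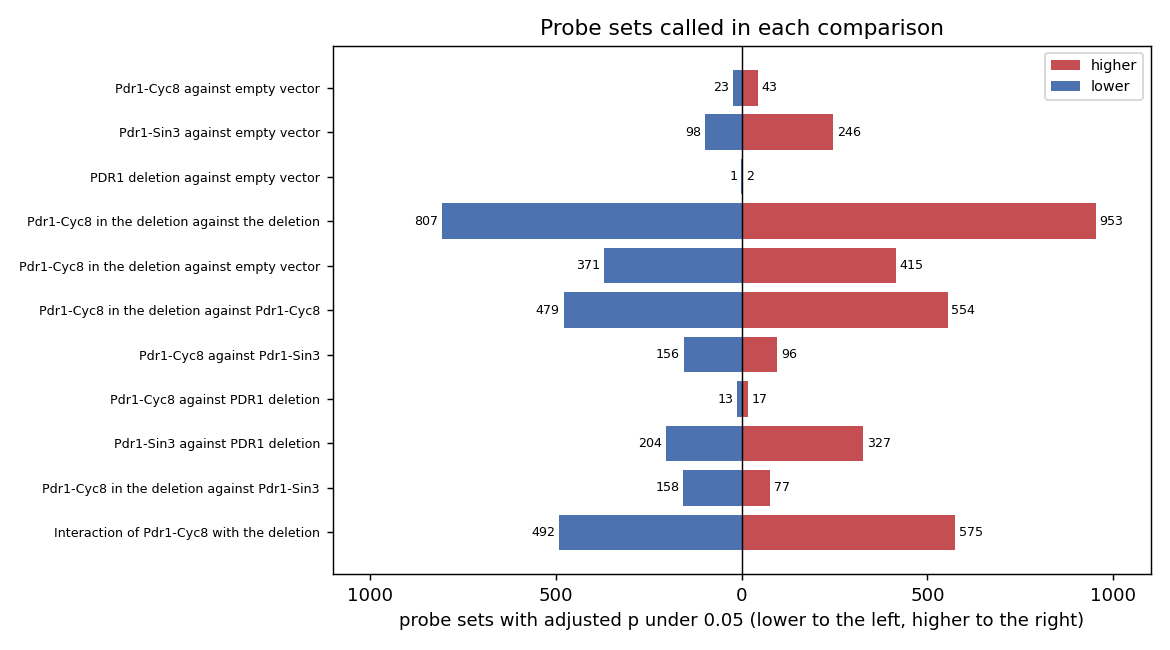
Number of probe sets (x axis) called higher or lower by limma in each comparison (y axis). Pdr1-Cyc8 in the deletion against the deletion had 953 higher and 807 lower, and the deletion against the empty vector had 2 higher and 1 lower.

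The Pdr1-Sin3 fusion was compared with the empty vector to address the same question with another corepressor; the groups lay in different sets of arrays. PDR5 fell by 2.14 (SE 0.326, adjusted p = 0.00213), from 10.84 ± 0.26 to 8.70 ± 0.51 (SD, n = 3), and SNQ2 fell by 0.99 (SE 0.263, adjusted p = 0.049). These were the 2 called among 22 PDR targets (4 with median centring), and 7 were lower adjusted over the list alone. YOR1 (-1.24, adjusted p = 0.0583), PDR16 (-0.95, adjusted p = 0.0527) and GRE2 (-0.71, adjusted p = 0.0618) did not pass by their brightest probe sets. Of 6 other YOR1 probe sets 1 passed (-1.42, adjusted p = 0.0417), and of 2 other TVS1 probe sets 1 (adjusted p = 0.0318). By camera, the PDR transporters were lower (mean -0.74, adjusted p = 0.0195, adjusted p = 0.323 with an estimated correlation), with 3 of 6 lower adjusted over the list alone, and so were the PDR lipid genes (mean -0.67, adjusted p = 0.041, adjusted p = 0.214 with an estimated correlation), with 3 of 5 lower adjusted over the list alone.

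Iron uptake genes rose with Pdr1-Sin3: FIT2 and FIT3, cell wall mannoproteins that retain siderophores, rose by 4.01 (SE 0.449, adjusted p = 0.000183) and 2.90 (SE 0.258, adjusted p = 2.53e-05), and the siderophore transporters ENB1 and SIT1 by 2.11 and 2.59 (adjusted p = 0.00174 each). Of 27 iron genes 9 rose and 1 fell, 15 and 1 adjusted over the list alone (camera adjusted p = 8.3e-07, adjusted p = 0.214 with an estimated correlation). Environmental stress genes also rose, 17 of 33, and 25 adjusted over the list alone (mean 1.29; camera adjusted p = 6.97e-19, adjusted p = 0.0828 with an estimated correlation), among them SOL4 by 3.06 and GLC3, the glycogen branching enzyme, by 2.48 (adjusted p = 0.000183 each). Of 16 phosphate genes 5 rose, 11 adjusted over the list alone (camera adjusted p = 2.94e-09, adjusted p = 0.0906 with an estimated correlation), such as PHO89, a phosphate cotransporter, by 2.10 (adjusted p = 0.00391) and VTC1, a subunit of the polyphosphate polymerase, by 1.29 (adjusted p = 0.00713). CYC1 and CYC7, isoforms of cytochrome c, changed in opposite directions, by -1.45 (adjusted p = 0.00832) and 2.21 (adjusted p = 0.0015). Ribosome assembly genes had 3 of 60 called lower, 15 adjusted over the list alone (camera adjusted p = 4.79e-09, adjusted p = 0.492 with an estimated correlation).

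Pdr1-Sin3 raised 246 and lowered 98 probe sets against the empty vector. The count was 186, 147, 130, 176 and 166 without empty vector replicates 1 and 2 and Pdr1-Sin3 replicates 1, 2 and 3. Of 17 genes named by size or as PDR targets and called, 10 stayed called whichever array was left out (SIN3, PDR5, FIT2, YOR387C, SOL4, FIT3, EGO4, NKP2, CYC1 and YVH1). SNQ2 lost its call without empty vector replicates 1, 2 or 3 (adjusted p = 0.132, 0.162 and 0.073) or Pdr1-Sin3 replicates 1, 2 or 3 (0.103, 0.143 and 0.11), with 0.0122 to 0.162 over all alternatives. Without the 3 arrays lowest in ribosome assembly genes 574 probe sets were called, and 770 with array weights.

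The loss of PDR1 was addressed by comparing the deletion with the empty vector, within the first set of arrays. PDR1 fell by 4.37 (SE 0.227, adjusted p = 1.66e-08). ENB1, a siderophore transporter, rose by 2.11 (SE 0.308, adjusted p = 0.0151), from 8.43 ± 0.28 to 10.54 ± 0.70 (SD, n = 3). The remaining call was a probe set without a listed gene, singled out here after its values were seen. It rose by 9.73 (SE 0.19, adjusted p = 9.04e-15), from 4.23 ± 0.05 with the empty vector, at the floor of the scale, to 13.97 ± 0.16 in the deletion, so the size of the rise is set by the pseudocount and only its presence is read here. In the group labelled as Pdr1-Cyc8 in the deletion it lay at 4.48 ± 0.27. The comparison may therefore hold a strain difference besides the loss of PDR1, and the sample titles of the deletion name no vector. None of the 22 PDR targets was called by limma, over all probe sets or adjusted over the list alone: PDR5 was -0.40 (adjusted p = 0.631), SNQ2 0.63 (adjusted p = 0.319), YOR1 0.70 (adjusted p = 0.386) and GRE2 0.19 (adjusted p = 0.727). Ribosome assembly genes were lower as a list (mean -1.11; camera adjusted p = 4.85e-27, adjusted p = 0.27 with an estimated correlation), with 0 of 60 called by limma and 45 lower adjusted over the list alone. Environmental stress genes were higher (mean 0.70; camera adjusted p = 6.59e-12, adjusted p = 0.142 with an estimated correlation), with 15 of 33 higher adjusted over the list alone, and iron genes (mean 0.77; camera adjusted p = 1.76e-07, adjusted p = 0.187 with an estimated correlation) had 1 of 27 called and 8 adjusted over the list alone.

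The 3 calls of the deletion stood against 1274 probe sets with an unadjusted p under 0.05. The count was 832 without deletion replicate 3 and 8 without empty vector replicate 2. ENB1 lost its call without empty vector replicates 1 or 3 or deletion replicates 1 or 2 (adjusted p = 0.0815, 0.119, 0.0756 and 0.149, from 0.000428 to 0.569 over all alternatives). Without the 3 arrays lowest in ribosome assembly genes 8 probe sets were called, and 196 with array weights.

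Pdr1-Cyc8 in the absence of endogenous PDR1 was addressed by comparing the deletion with and without the fusion, across the sets of arrays. The groups also differed at the probe set without a listed gene described above, so the comparison, and the interaction below, may hold a strain difference besides the fusion. YOR1 fell by 3.75 (SE 0.342, adjusted p = 1.08e-05), from 10.75 ± 0.81 in the deletion (SD, n = 3). The pumps SNQ2 (-2.84, SE 0.263, adjusted p = 1.19e-05), PDR15 (-1.26, SE 0.275, adjusted p = 0.00638) and PDR5 (-1.24, SE 0.326, adjusted p = 0.0173) also fell. So did GRE2 (-2.88, SE 0.198, adjusted p = 1.03e-06), PDR16 (-2.09, SE 0.256, adjusted p = 0.000122), TVS1 (-2.03, SE 0.238, adjusted p = 8.49e-05) and ICT1, a lysophosphatidic acid acyltransferase (-2.68, SE 0.424, adjusted p = 0.000951). Of 22 PDR targets 14 fell (12 with the values as deposited); adjusted over the list alone 17 were lower and 1 was higher, RSB1, whose signal was near the floor in both groups, so no fold is given. All 3 PDR lists were lower by camera: the transporters (4 of 6 called, 6 adjusted over the list alone, adjusted p = 3.28e-06, adjusted p = 0.0828 with an estimated correlation), the lipid genes (4 of 5 called, 4 lower and 1 higher adjusted over the list alone, adjusted p = 0.00159, adjusted p = 0.0884 with an estimated correlation) and the other targets (6 of 11 by either count, adjusted p = 5.7e-06, adjusted p = 0.165 with an estimated correlation). Without deletion replicates 1 and 2 and Pdr1-Cyc8 replicate 1, PDR5 (-1.60), PDR15 (-0.80) and ICT1 (-1.84) lost their calls. That fit left 1 deletion array, assumed to vary like the other groups. Adjusted p over all alternatives ran from 0.00194 to 0.14 for PDR15 and from 0.000226 to 0.0817 for ICT1. PDR5 also lost its call without deletion replicate 2 or Pdr1-Cyc8-in-deletion replicate 3 (adjusted p = 0.0626 and 0.0786, from 0.0104 to 0.0786 over all alternatives).

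Beyond the PDR lists, HXT2, a glucose transporter, rose by 4.11 (SE 0.55, adjusted p = 0.000275), FLO1 by 3.96 (SE 0.401, adjusted p = 1.97e-05) and HPF1, a cell wall mannoprotein, by 3.21 (SE 0.506, adjusted p = 0.00094). ARG1, of arginine synthesis, fell by 3.88 (SE 0.702, adjusted p = 0.00213). INO1, inositol phosphate synthase, fell by 3.70 (SE 0.493, adjusted p = 0.000272), and YGP1, a secreted glycoprotein, fell by 3.62 (SE 0.286, adjusted p = 3.71e-06). Of 48 amino acid synthesis genes 16 fell, 20 adjusted over the list alone (mean -1.10; camera adjusted p = 4.21e-09, adjusted p = 0.33 with an estimated correlation), among them HIS4 (-2.06, adjusted p = 0.000995). This list averaged 0.51 ± 0.70 (SD, n = 3) in the deletion cultures against the empty vector, from -0.28 to 1.02, and -0.60 ± 0.03 with the fusion in the deletion. Ribosome assembly genes rose in 26 of 60 cases, 36 adjusted over the list alone (mean 1.07; camera adjusted p = 1.56e-10, adjusted p = 0.458 with an estimated correlation), for example GAR1, of box H/ACA particles, by 2.14 (adjusted p = 0.00192). Against the empty vector this list averaged -1.50, -1.71 and -0.13 in deletion replicates 1, 2 and 3 and -0.05, 0.00 and -0.09 in the cultures with the fusion in the deletion. Proteasome genes rose in 14 of 32 cases, 15 adjusted over the list alone (camera adjusted p = 8.77e-05, adjusted p = 0.165 with an estimated correlation), with RPN3 up by 1.17 (adjusted p = 0.00238). Of 27 iron genes 10 fell and 1 rose, 16 and 2 adjusted over the list alone (camera adjusted p = 2.02e-05, adjusted p = 0.27 with an estimated correlation). Iron genes averaged 0.77 ± 0.26 (SD, n = 3) in the deletion against the empty vector, and -0.03 ± 0.04 with the fusion in the deletion.

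In total 953 probe sets rose and 807 fell. The fitted count was 1160 and 998 without deletion replicates 1 and 2, and 1102, 1152 and 1153 without Pdr1-Cyc8-in-deletion replicates 1, 2 and 3. Without the 3 arrays lowest in ribosome assembly genes it was 309, and with only these groups in the fit 925. Of 30 genes named in the same way and called, 24 stayed called whichever array was left out. Without those 3 arrays ARG1 (-1.76), GAR1 (1.12) and RPN3 (0.90) lost their calls, with a highest adjusted p over all alternatives of 0.0598, 0.0508 and 0.117. The probe set without a listed gene that was present in the deletion lay near the floor of the scale with the fusion in the deletion, although both are labelled as deletions of PDR1.

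Pdr1-Cyc8 in the deletion differed from the empty vector in both the fusion and the deletion. Of 22 PDR targets 10 were lower in it, 13 adjusted over the list alone. They included YOR1 (-3.06, SE 0.342, adjusted p = 8.44e-05), GRE2 (-2.69, SE 0.198, adjusted p = 4.75e-06), PDR16 (-2.52, SE 0.256, adjusted p = 3.52e-05), SNQ2 (-2.22, SE 0.263, adjusted p = 0.000126) and PDR5 (-1.64, SE 0.326, adjusted p = 0.0064). FLO1 rose by 3.90 (adjusted p = 3.57e-05), HXT2 by 3.83 (adjusted p = 0.000619) and CYC7 by 3.03 (adjusted p = 4.01e-05), while MIG2 fell by 3.37 (adjusted p = 1.88e-05). The PDR lipid genes had 4 of 5 members lower by either count (camera adjusted p = 3.08e-05, adjusted p = 0.0656 with an estimated correlation). The comparison crossed the sets of arrays and called 415 probe sets higher and 371 lower, with 366 calls without empty vector replicate 2, 458 and 464 without Pdr1-Cyc8-in-deletion replicates 1 and 3, and 1215 with array weights. Of 17 named and called genes 16 stayed called whichever array was left out. With the values as deposited 67.0% of calls were higher in place of 52.8%, with a median of all probe sets of 0.14, and with median centring 44.4% were higher, with a median of -0.02. Which direction had more calls therefore depended on the scaling.

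The fusion with and without endogenous PDR1 was compared directly between the Pdr1-Cyc8 groups, again across the sets of arrays. YOR1 (-2.36, SE 0.342, adjusted p = 0.000948), SNQ2 (-1.79, SE 0.263, adjusted p = 0.001) and GRE2 (-1.11, SE 0.198, adjusted p = 0.00411) were lower in the deletion. In all, 5 of 22 PDR targets were called lower, with 8 lower and 1 higher, RTA1, near the floor in both groups, adjusted over the list alone. PHO84 was higher by 3.46 (SE 0.716, adjusted p = 0.00824) and HPF1 by 3.05 (SE 0.506, adjusted p = 0.00242), while ARG1 (-3.79, adjusted p = 0.00477) and INO1 (-3.24, adjusted p = 0.00132) were lower. Amino acid synthesis genes were lower, 12 of 48 called and 17 adjusted over the list alone (camera adjusted p = 3.66e-11, adjusted p = 0.27 with an estimated correlation). Of 1033 calls, 554 were higher and 479 lower. There were 429 and 637 calls without Pdr1-Cyc8 replicates 1 and 2, 537, 623 and 530 without Pdr1-Cyc8-in-deletion replicates 1, 2 and 3, and 654 without the 3 arrays lowest in ribosome assembly genes; 9 of 12 named and called genes stayed called whichever array was left out. With the values as deposited the median of all probe sets was 0.10 in place of 0.03.

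Whether the effect of Pdr1-Cyc8 differs with the endogenous gene was tested as an interaction, the fusion's effect in the deletion minus its effect without. It was negative for YOR1 (-3.05, SE 0.484, adjusted p = 0.0028), SNQ2 (-2.42, SE 0.372, adjusted p = 0.00238) and GRE2 (-1.30, SE 0.28, adjusted p = 0.0123), and for PDR15 (-1.55, adjusted p = 0.0219) and TVS1 (-1.40, adjusted p = 0.0191), the 5 of 22 PDR targets called, and 5 adjusted over the list alone. PDR5 had 0.97 (adjusted p = 0.179). Positive interactions included PHO84 (4.38, SE 1.01, adjusted p = 0.0161) and YBR219C (3.49, SE 0.453, adjusted p = 0.000628), and negative ones ARO9 (-5.77, SE 1.09, adjusted p = 0.00702) and ARO10 (-5.93, SE 1.30, adjusted p = 0.0129), enzymes of aromatic amino acid breakdown. Of 60 ribosome assembly genes 33 had a positive interaction, 51 adjusted over the list alone (camera adjusted p = 3.94e-18, adjusted p = 0.373 with an estimated correlation), and 15 of 48 amino acid synthesis genes a negative one, 18 adjusted over the list alone (camera adjusted p = 1.56e-10, adjusted p = 0.28 with an estimated correlation). Against the empty vector the ribosome assembly list ranged from -1.71 to -0.13 over the deletion cultures and from -1.30 to -0.47 with Pdr1-Cyc8. In total 575 interactions were positive and 492 negative. The count was 436 without empty vector replicate 1, 442 without Pdr1-Cyc8 replicate 1, 627, 462 and 1805 without deletion replicates 1, 2 and 3, and 609, 709 and 668 without Pdr1-Cyc8-in-deletion replicates 1, 2 and 3. Of 12 named and called genes 10 stayed called whichever array was left out. Without the 3 arrays lowest in ribosome assembly genes 51 were called, among them 42 of the 1067, and SNQ2, YOR1, GRE2, PDR15, TVS1, PHO84, ARO9 and ARO10 lost their calls (highest adjusted p over all alternatives 0.0672, 0.0672, 0.087, 0.296, 0.26, 0.249, 0.0773 and 0.135). PDR15 and TVS1 also lost theirs without empty vector replicate 1 (0.0635 and 0.0547) or Pdr1-Cyc8 replicate 1 (0.0627 and 0.0534), and PDR15 without deletion replicate 2 (0.058), with lowest adjusted p over all alternatives of 0.00491 and 0.00951. The fit without the 3 arrays left 1 deletion array, so a call lost there does not show that the interaction was absent.

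The fusions were compared with each other and with the deletion. Between Pdr1-Cyc8 and Pdr1-Sin3, PHO84 (-4.97, SE 0.716, adjusted p = 0.0017), PHO5 (-3.78, SE 0.435, adjusted p = 0.000237) and SPL2, a regulator of phosphate transporters (-3.76, SE 0.47, adjusted p = 0.000546), were lower with Pdr1-Cyc8. Of 16 phosphate genes 12 were lower by either count (camera adjusted p = 4.84e-17, adjusted p = 0.0656 with an estimated correlation). GRE2 (-0.87, adjusted p = 0.0312) was the single PDR target called (0 by limma with the values as deposited), and the count adjusted over the list alone was also 1. The comparison called 96 probe sets higher and 156 lower. In place of 252 calls there were 93 without Pdr1-Cyc8 replicate 1, 83, 117 and 132 without Pdr1-Sin3 replicates 1, 2 and 3, and 126 without the 3 arrays lowest in ribosome assembly genes. Of 8 named and called genes 5 stayed called whichever array was left out. GRE2 lost its call without Pdr1-Cyc8 replicates 1 or 2 (adjusted p = 0.133 and 0.0565) or Pdr1-Sin3 replicates 1, 2 or 3 (0.072, 0.0757 and 0.109), with 0.0159 to 0.133 over all alternatives.

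The Pdr1-Cyc8 group differed from the deletion in endogenous PDR1 and at the probe set without a listed gene, besides the fusion. Their differences are therefore not assigned to the fusion alone. Against the deletion and within the first set of arrays, PDR5 (-1.80, SE 0.326, adjusted p = 0.0211), GRE2 (-1.77, SE 0.198, adjusted p = 0.000191) and PDR3, which encodes a transcription factor related to Pdr1 (-1.05, SE 0.184, adjusted p = 0.0196), were lower with Pdr1-Cyc8. These were 3 of 22 PDR targets, and 12 were lower adjusted over the list alone. Of 6 other YOR1 probe sets 1 was called (-1.62, adjusted p = 0.0423), although the brightest was not. The other PDR targets (camera adjusted p = 1.07e-10, adjusted p = 0.0828 with an estimated correlation) had 2 of 11 called and 6 adjusted over the list alone. There were 17 probe sets higher and 13 lower, and 15, 12, 17 and 51 calls without Pdr1-Cyc8 replicates 1 and 2 and deletion replicates 2 and 3. Of 7 named and called genes 3 stayed called whichever array was left out. PDR5 lost its call without Pdr1-Cyc8 replicates 1, 2 or 3 (adjusted p = 0.11, 0.0661 and 0.0824) or deletion replicates 2 or 3 (0.123 and 0.0563), with 0.0116 to 0.193 over all alternatives. PDR3 lost it without Pdr1-Cyc8 replicates 1, 2 or 3 (0.0505, 0.0727 and 0.0795) or deletion replicates 1 or 2 (0.0705 and 0.107), with 0.00726 to 0.454 over all alternatives. Pseudocount 1 gave 16 calls, a fit of only these groups 14 and a fit of only the first set 15.

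The Pdr1-Sin3 group likewise differed from the deletion in endogenous PDR1, at the probe set without a listed gene and in the set of arrays, besides the fusion. Against the deletion, YOR1 (-1.93, SE 0.342, adjusted p = 0.00446), PDR5 (-1.74, SE 0.326, adjusted p = 0.00664) and SNQ2 (-1.62, SE 0.263, adjusted p = 0.00261) were lower with Pdr1-Sin3. They were among 6 of 22 PDR targets called lower, with 9 lower and 1 higher, YGR035C, near the floor in the deletion, adjusted over the list alone. YOR387C and VEL1 rose by 4.13 (SE 0.448, adjusted p = 0.000124) and 3.53 (SE 0.455, adjusted p = 0.000596), and 9 of 16 phosphate genes rose, 13 adjusted over the list alone (camera adjusted p = 2.32e-10, adjusted p = 0.0828 with an estimated correlation). The comparison called 327 probe sets higher and 204 lower. The count was 301, 232 and 1049 without deletion replicates 1, 2 and 3, 174, 238 and 351 without Pdr1-Sin3 replicates 1, 2 and 3, and 117 without the 3 arrays lowest in ribosome assembly genes. In that last fit YOR1 and SNQ2 lost their calls (adjusted p over all alternatives from 0.00034 to 0.144 and from 0.000415 to 0.145). Of 13 named and called genes 8 stayed called whichever array was left out.

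Pdr1-Cyc8 in the deletion and Pdr1-Sin3 shared the second set of arrays, and their comparison was added after the data were seen. In the former GRE2 (-1.98, SE 0.198, adjusted p = 3.76e-05), YOR1 (-1.82, SE 0.342, adjusted p = 0.0116), PDR16 (-1.57, SE 0.256, adjusted p = 0.00492) and SNQ2 (-1.23, SE 0.263, adjusted p = 0.0226) were lower. They were among 5 PDR targets of 22 called lower, 10 adjusted over the list alone. Of 2 other TVS1 probe sets 1 was called (-1.31, adjusted p = 0.0363), although the brightest was not. FIT2, MIG2 and FLO1 differed by -4.04 (SE 0.449, adjusted p = 0.00011), -4.03 (SE 0.315, adjusted p = 6.2e-06) and 3.56 (SE 0.401, adjusted p = 0.000118). Of 27 iron genes 7 were lower, 14 adjusted over the list alone (camera adjusted p = 2.33e-12, adjusted p = 0.0688 with an estimated correlation). List tests of this comparison were adjusted over 33 tests in place of 330, so their adjusted p-values are not comparable with those of the other comparisons. On that smaller scale 2 lists kept their call with an estimated correlation. The PDR lipid genes had 1 of 5 lower and 4 adjusted over the list alone (camera adjusted p = 0.000448, adjusted p = 0.0427 with an estimated correlation). The phosphate genes had 4 of 16 lower and 12 adjusted over the list alone (camera adjusted p = 2.16e-12, adjusted p = 0.0427 with an estimated correlation). There were 77 probe sets higher and 158 lower. The count was 99, 104 and 132 without Pdr1-Cyc8-in-deletion replicates 1, 2 and 3 and 67 and 70 without Pdr1-Sin3 replicates 1 and 3, and 9 of 13 named and called genes stayed called whichever array was left out. SNQ2 lost its call without replicates 1 or 2 of the former (adjusted p = 0.0763 and 0.0874) or replicates 1 or 3 of Pdr1-Sin3 (0.098 and 0.0913), with 0.00648 to 0.098 over all alternatives. With the values as deposited 45.0% of calls were higher in place of 32.8%, and with median centring 24.0%.

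Overlap was examined between comparisons that use the same empty vector arrays. Pdr1-Cyc8 and Pdr1-Sin3 had 25 probe sets higher in both and 9 lower in both, where independent lists would share 1.14 and 0.24. Simulated groups shared 0, but they held no change to call and no correlation between genes, so this is no benchmark for shared calls. PHO5 was called in opposite directions by Pdr1-Cyc8 and Pdr1-Sin3 (-2.10 and 1.68). The log2 fold changes of the 2 fusions correlated across probe sets, which are not independent replicates, at 0.431 (simulated 0.498), with a covariance of 0.0986 (simulated 0.0479, difference 0.0508). For Pdr1-Cyc8 and the deletion 0 limma calls were shared, where independent lists would share 0.01 higher; the correlation was 0.652 (simulated 0.481) and the covariance 0.1338 (simulated 0.0456). Pdr1-Sin3 and the deletion shared 1 higher call, ENB1, against 0.05 for independent lists, with a correlation of 0.322 (simulated 0.507) and a covariance of 0.0812 (simulated 0.0483). With 3 control arrays a split into separate control groups of 2 was not possible, so part of any excess may come from the shared controls. All comparisons also used 1 estimate of spread per probe set, from the same fit. Probe sets with a small spread are more readily called in each comparison. Independent lists are therefore no exact benchmark, with or without shared arrays. The effects of Pdr1-Cyc8 without and with the deletion, which share no array, had 18 higher and 15 lower calls in common, against 4.42 and 2, and a correlation of -0.198. GSY2, RSC8, HER1 and a probe set without a listed gene, named after their values were seen, were called in opposite directions. The fusions shared 14, 17, 9 and 20 calls without empty vector replicates 1 and 3 and Pdr1-Cyc8 replicates 1 and 2. Pdr1-Cyc8 and the deletion shared 5, 1 and 46 without empty vector replicate 2, Pdr1-Cyc8 replicate 3 and deletion replicate 3. Pdr1-Sin3 and the deletion shared 6 and 131 without empty vector replicate 2 and deletion replicate 3, and 0 limma calls without empty vector replicates 1 or 3 or deletion replicates 1 or 2. The effects of Pdr1-Cyc8 shared 18, 21 and 15 without empty vector replicates 1 and 3 and Pdr1-Cyc8 replicate 1.

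**Figure D3:**
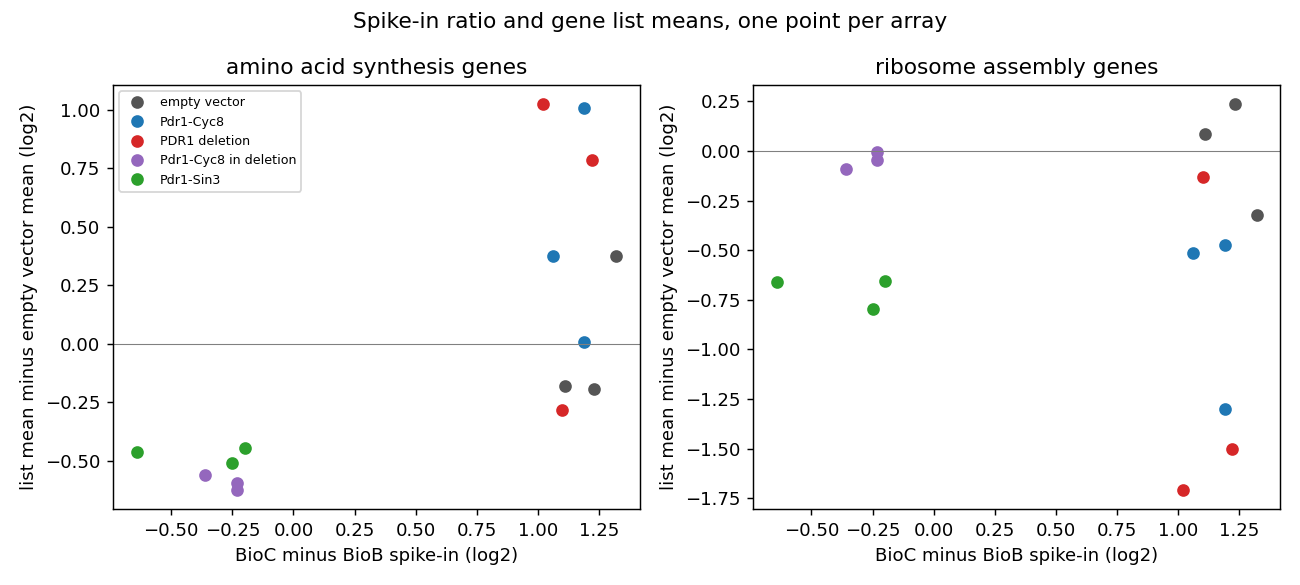
Mean log2 difference of a gene list from the empty vector mean (y axis) against the log2 difference between the BioC and BioB spike-ins (x axis). The panels show amino acid synthesis and ribosome assembly genes, with a point for each of the 15 arrays, coloured by group. On the x axis the 9 arrays of the empty vector, Pdr1-Cyc8 and deletion groups lay between 1.02 and 1.32, and the other 6 between -0.64 and -0.20.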

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

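Of the tests below, those for amino acid synthesis and PDR genes were chosen only after the results were seen. The splits and relabellings of the arrays were written before. The test of the small count for the deletion starts from that count, so it was not chosen independently of the result.

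The interaction of Pdr1-Cyc8 with the deletion drew attention because the fusion's effect differed between the groups with and without the gene, at 1067 probe sets. Log2 interactions were positive for PHO84 (4.38), HPF1 (3.65), YBR219C (3.49), YDR034C-A (3.44), PHO5 (2.86), YKR075C (2.28) and PDR1 (2.25). They were negative for ARO10 (-5.93), ARO9 (-5.77), ARG3 (-5.58), ARG1 (-5.35), YOR302W (-4.18), INO1 (-3.95), YOR1 (-3.05), ICY1 (-2.93), YGP1 (-2.56), SNQ2 (-2.42), GSY1 (-1.83), PDR15 (-1.55), SHC1 (-1.44), TVS1 (-1.40) and GRE2 (-1.30). Among 100 relabellings of fusion and no fusion within each strain background 1, the real one, had as many calls, and the highest other count was 915. Such relabelling breaks up any effect of the fusion, not only an interaction. In the deletion it also breaks up the spike-in sets, so the rank of the real count cannot show an interaction, and nothing is concluded from it. All the interactions compare arrays of different spike-in sets, and the deletion groups with and without the fusion also differed at a probe set without a listed gene.

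Of 48 amino acid synthesis genes, 16 were called lower with Pdr1-Cyc8 in the deletion than in the deletion, 20 adjusted over the list alone (camera adjusted p = 4.21e-09, adjusted p = 0.33 with an estimated correlation). If the spike-in set accounted for this, the list should differ little within the second set and fall between sets. It differed by -0.122 between the groups of the second set and by -0.983 for Pdr1-Sin3 against the deletion, which is consistent with a difference between the sets of arrays, while Pdr1-Cyc8 against the empty vector within the first set gave 0.463. Without deletion replicates 1 and 2 the list was -0.311 and 265 probe sets were called, but this leaves 1 deletion array, assumed to vary like the other groups, and decides nothing about the state of those cultures. The fall may be technical in part, and the data do not attribute it to the fusion.

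PDR genes fell with Pdr1-Cyc8 in the deletion, 14 of 22 by call. Of these 14, 4 were also lower against Pdr1-Sin3 within the second set, which leaves the spike-in set open for the others, since Pdr1-Sin3 is itself a fusion that could lower them. Against the empty vector, a difference of means without the deletion cultures, 9 of the 14 were also called lower, so the state of the deletion cultures alone does not account for these 9 (5 of the 14 were called lower with deletion replicate 3 as the only deletion array). A biological explanation is that endogenous Pdr1 weakens the fusion, and 5 of the 14 had a called negative interaction (6 by unadjusted p). PDR5 (0.97, limma adjusted p = 0.179) and IPT1 (0.26, adjusted p = 0.762) had positive values, opposite to this explanation but not called. The others of the 14 were below 0. Because the interaction crosses the sets, the tests do not decide between these explanations.

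Few probe sets, 3, were called for the deletion against the empty vector. Without deletion replicate 3 there were 832, against 4 without replicate 1 and 2 without replicate 2. Replicate 3 lay apart from replicates 1 and 2 in ribosome assembly genes, as given above. Leaving out an array that lies apart lowers the spread, so a rise in calls could be foreseen and does not test the reason for the small count. The small count depended on this array, so it does not show that the deletion had no effect.

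For counts of calls, every other way of splitting the arrays of a comparison into 3 against 3 was also tested, and 10 splits are too few for a share under 0.05. The number of splits with at least the real count was 1 for Pdr1-Cyc8 against the empty vector (66, highest other 1), 1 for Pdr1-Sin3 against the empty vector (344, highest other 0) and 2 for the deletion against the empty vector (3, highest other 213). It was 1 for Pdr1-Cyc8 in the deletion against the deletion (1760, highest other 0), 1 against the empty vector (786, highest other 0), 1 against Pdr1-Cyc8 (1033, highest other 1) and 1 against Pdr1-Sin3 (235, highest other 1). It was 1 for Pdr1-Cyc8 against Pdr1-Sin3 (252, highest other 0), 2 for Pdr1-Cyc8 against the deletion (30, highest other 671) and 1 for Pdr1-Sin3 against the deletion (531, highest other 1).

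Control probe sets outside the main measurement, 60 in 4 comparisons, gave 15 results above the empty vector. They were fitted apart from the genes, on log2 values as deposited, with limma p-values adjusted over these 60 in each comparison. Their adjusted p-values are therefore not on the scale of the gene results. With Pdr1-Sin3 all 5 probe sets for 18S rRNA were higher, by 1.38, 1.51, 1.04, 1.64 and 0.90, and 3 of 5 for 25S rRNA, by 1.07, 1.03 and 1.66, while the others were at -0.60 (adjusted p = 0.206) and 0.51 (adjusted p = 0.313). Of 4 CreX spike-in probe sets 3 were higher, by 0.69, 1.68 and 0.64, and the other was at 0.34 (adjusted p = 0.508). MurIL2 was higher by 0.96, at 5.37 against 4.42. With the empty vector the rRNA probe sets called higher lay from 4.20 to 6.13 and the CreX probe set with 1.68 at 4.99, against a floor of 4. The sizes of these differences and of that of MurIL2 therefore depended on the pseudocount, and only their direction is read. The BioC spike-in probe sets, which mark the sets of arrays, were lower with Pdr1-Sin3 (-1.23 and -0.84) and with Pdr1-Cyc8 in the deletion (-1.93 and -1.33). In the deletion 1 probe set for 18S rRNA was higher by 1. With Pdr1-Cyc8 in the deletion 1 for 18S rRNA was higher by 0.90 and 1 for 25S rRNA by 1.36.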

How the results depend on the processing

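No named call changed direction under any alternative. A gene not called stayed counted as unchanged while uncalled, whatever its sign. No list call changed direction in the alternatives in which lists were tested again. These were an estimated correlation, fry, the values as deposited, the fit without the dimmest probe sets, the mean of all probe sets of a gene, the replicate block and leaving out each array. Lists were not tested again in the other fits, such as that without the 3 arrays lowest in ribosome assembly genes. Of counts, 95 alternatives other than leaving out 1 array stayed within 1.5 times and 36 did not; of 393 named calls, leaving out the 3 arrays lowest in ribosome assembly genes ended 157, a fit of only the groups compared 86, a pseudocount of 1 ended 73, the values as deposited 23 and median centring 20. The direction with more calls changed in some fits. For the deletion against the empty vector 66.7% of 3 calls were higher, 38.3% with array weights, 25.0% without the 3 arrays and 44.1% and 25.0% without deletion replicates 3 and 1. For Pdr1-Cyc8 in the deletion against the empty vector the share was 52.8%, 44.4% with median centring, 49.1% without the dimmest probe sets, 49.9% with only the groups compared and 46.7% without its replicate 2. Against the deletion it was 54.1%, 49.6% with only the groups compared and 48.3% without deletion replicate 2, and against Pdr1-Cyc8 it was 53.6%, with 49.2%, 49.1% and 49.0% for only the groups compared, without the 3 arrays and without replicate 2 of the former. For the interaction it was 53.9%, 47.1% without the 3 arrays and 49.6% without Pdr1-Cyc8-in-deletion replicate 2. A pseudocount of 1 gave 36 calls for Pdr1-Cyc8 against the empty vector, 134 against Pdr1-Sin3 and 16 against the deletion, 341 for Pdr1-Sin3 against the deletion, 142 for Pdr1-Cyc8 in the deletion against Pdr1-Sin3 and 710 for the interaction. A fit of only the groups compared gave 10, 143, 14, 200 and 414 for these comparisons in the same order, apart from the interaction, and 925 for Pdr1-Cyc8 in the deletion against the deletion. Array weights gave 109, 770 and 196 against the empty vector for Pdr1-Cyc8, Pdr1-Sin3 and the deletion, 1215 for Pdr1-Cyc8 in the deletion, 435 for Pdr1-Cyc8 against Pdr1-Sin3, 834 for Pdr1-Sin3 against the deletion and 533 for Pdr1-Cyc8 in the deletion against Pdr1-Sin3. Without the 3 arrays lowest in ribosome assembly genes the counts were 40, 574 and 8 against the empty vector, 309, 654 and 440 for Pdr1-Cyc8 in the deletion against the deletion, Pdr1-Cyc8 and Pdr1-Sin3, 126 for Pdr1-Cyc8 against Pdr1-Sin3, 117 for Pdr1-Sin3 against the deletion and 51 for the interaction. Only the first set gave 19 and 15 for Pdr1-Cyc8 against the empty vector and the deletion. An estimated correlation left 0 of 127 list calls. Shared calls of the deletion with Pdr1-Cyc8 and with Pdr1-Sin3 were 2 and 2 as deposited, and 2 and 2 without the dimmest probe sets. Why the counts and shares moved in these fits was not tested.

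Leaving out 1 array gave 18 to 59 calls for Pdr1-Cyc8 against the empty vector, 130 to 243 for Pdr1-Sin3, 2 to 832 for the deletion and 366 to 545 for Pdr1-Cyc8 in the deletion. It gave 998 to 2224 for the latter against the deletion, 429 to 934 against Pdr1-Cyc8 and 67 to 175 against Pdr1-Sin3, 83 to 221 for Pdr1-Cyc8 against Pdr1-Sin3, 12 to 51 against the deletion, 174 to 1049 for Pdr1-Sin3 against the deletion, 436 to 1805 for the interaction and 119 to 131 for gene lists. Shared calls ranged from 9 to 28 for the fusions, 0 to 46 and 0 to 131 for the deletion with Pdr1-Cyc8 and Pdr1-Sin3, and 15 to 37 for Pdr1-Cyc8 without and with the deletion. With the replicate block, in which arrays share only a number, 1 call was shared by Pdr1-Cyc8 and the deletion, no other count moved by over 1.5 times and 26 of 393 named calls ended; at most 1 of 3 arrays correlated best with its own number, and no comparison had all 3 correlations over 0.1 (0.233, -0.027 and 0.334 for Pdr1-Cyc8 against the deletion). With 835 to 1364 probe sets per array under a signal of 16, fold changes of dim genes were compressed by the pseudocount.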

Other observations

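Signals of probe sets for small RNAs differed between groups. These genes were not tested as a set, and whether the signals follow the levels of the mature RNAs was not tested. Over all 5656 genes, Pdr1-Cyc8 in the deletion had 302 calls higher than the empty vector, 691 than the deletion and 386 than Pdr1-Cyc8. Of 91 tRNA genes, 46 were called higher with Pdr1-Cyc8 in the deletion than with the empty vector (median 1.08 on the log2 scale), 44 higher than in the deletion (0.96) and 29 higher than with Pdr1-Cyc8 (0.83). With Pdr1-Sin3 18 were higher than with the empty vector (0.75) and 13 higher than in the deletion (0.47). Within a spike-in set the median differed less: 0.28 between Pdr1-Cyc8 in the deletion and Pdr1-Sin3, with 5 called, 0.23 for Pdr1-Cyc8 and 0.20 for the deletion against the empty vector, with 0 called by limma in either. A test of the spike-in set as the source of this difference was run and then set aside after its result, which was undecided, had been seen. Of 57 snoRNA genes, 25 were higher with Pdr1-Cyc8 in the deletion than in the deletion (median 0.80), 10 higher than with the empty vector (0.40), and 5 higher with Pdr1-Sin3 than with the empty vector (0.24). Within a set the snoRNA medians were -0.29 for Pdr1-Cyc8 and -0.30 for the deletion against the empty vector and 0.17 between Pdr1-Cyc8 in the deletion and Pdr1-Sin3. As deposited, 58 tRNA and 16 snoRNA genes were higher with Pdr1-Cyc8 in the deletion than with the empty vector.

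Some mating genes were lower with Pdr1-Cyc8 in the deletion than in the deletion, a comparison across the spike-in sets. SST2, a regulator of pheromone signalling, fell by 1.80 (adjusted p = 0.000102), AGA1, an agglutinin subunit, fell by 2.04 (adjusted p = 0.000398) and BAR1, the alpha-factor protease, fell by 1.64 (adjusted p = 0.000907). Of 20 haploid and mating genes 5 fell and 1 rose, 8 and 1 adjusted over the list alone (camera adjusted p = 0.000792, adjusted p = 0.142 with an estimated correlation), and of 7 a-specific genes 5 fell by either count (camera adjusted p = 0.000243, adjusted p = 0.249 with an estimated correlation). Against the empty vector the a-specific genes averaged 0.87, 1.07 and 0.16 in deletion replicates 1, 2 and 3.

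The probe set without a listed gene that rose in the deletion, chosen after its values were seen, had a log2 level of 13.97 in the deletion and 4.22 to 4.48 as the mean of each other group. The group labelled as Pdr1-Cyc8 in the deletion was thus not raised, while its PDR1 was below the empty vector (-2.14, adjusted p = 4.92e-05), and what the probe set detects was not tested.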
